A study of Mus musculus with 16 samples.

How the data were processed

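RNA was measured in 16 libraries of CD4-positive T cells sorted from mice, in 4 groups of 4. Per the labels' protocols, cells were enriched for CD4 and then sorted by flow cytometry, cDNA was made with the SMART-Seq v4 kit, libraries were made by tagmentation with Nextera XT and sequenced in paired reads of 150 bp on a NextSeq 500. Neither kit marks the strand of the RNA, so reads of overlapping and antisense genes cannot be told apart. Per the submitters' processing notes, the tools were Trimmomatic, HISAT2, SAMtools, featureCounts and DESeq2 and the genome build was GRCm38; versions and settings are not given in the sources used here. The deposited values are counts of reads per gene from the authors, not normalized, for 49585 genes. A table of the whole series and 16 files of single libraries were deposited, and the single-library counts were identical to the table in 16 of 16 cases. Gene identifiers were matched to symbols, biotypes and GRCm38 coordinates in the GENCODE M21 annotation, which named 49326 of them.

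Replicates are pools of mice: per the labels, each pool held 20 animals where mice were not pregnant, and between 3 and 8 where they were. Groups came from the labels alone. The labels also state that sequencing was done in 2 batches. Uterine CD4conv and pregnant uterine Treg were in batch 1. Lymph node Treg and non-pregnant uterine Treg were in batch 2. The tissue comparison and the comparison of pregnant uterine Treg with CD4conv therefore lie within a batch, while the cell type and pregnancy comparisons cross the batches and cannot carry batch as a term in the model.

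Levels are counts per 1e6 counts of the library (CPM), given as mean ± SD over 4 libraries. Group differences were tested on the deposited counts with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr, robust fit over all 16 libraries, 12 residual degrees of freedom) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05; 30096 genes passed the filter. Fold changes are log2. Their standard error (SE) was derived as the absolute log2 fold change divided by the square root of the F statistic of the edgeR test. Gene lists, 31 in all, were fixed before the data were examined and cover T cell programs, signalling responses, metabolism and markers of other cell types. The 30 lists with at least 3 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Each list call was repeated with an estimated correlation and with fry, which asks whether a list's genes move on balance in one direction and does not compare them with other genes. Library composition was compared by exact permutation tests, two-sided, over 70 arrangements, whose smallest possible p is 0.0286.

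The libraries hold reads in genes that are silent in T cells (see the results), so every test was repeated on genes above background. These were the 4723 tested protein-coding genes whose mean share of counts over all 16 libraries exceeded 5 times the background. The background was estimated per exonic base from 1427 olfactory and vomeronasal receptor genes. The set of genes above background was chosen after seeing the data. The planned counts of genes over all genes stand beside it, but not the planned result of every named gene. In these genes 21 lists had enough members. Restricting the genes moved the mean log2 TMM scaling between groups by 0.31 (tissue), 0.42 (cell type), 0.07 (pregnancy) and 0.48 (pregnant Treg against CD4conv). Fold changes did not all move by these amounts. The median log2 fold change of these genes went from -0.223 to 0.048 (tissue) and from -0.292 to 0.020 (cell type). It went from 0.054 to 0.0035 (pregnancy) and from -0.227 to 0.031 (pregnant Treg against CD4conv). The square root of the common dispersion, the coefficient of variation between replicates, was 0.812 over all genes and 0.433 in genes above background.

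Genes named in the text followed a rule written before the data were examined. It takes Foxp3 and Il2ra, and the 8 highest and 8 lowest fold changes (5 and 5 for pregnant Treg against CD4conv) among protein-coding genes past the threshold with at least 20 CPM in the higher group and no overlap between the 4 libraries of each group, an arrangement that chance gives with probability 0.0286. It leaves out antigen receptor segments. It adds up to 4 members of each list described, at 5 CPM or more, and fixed genes that include Areg, Gata3, Il1rl1, Il10, Ccr7 and Mki67. Some genes the rule takes are not reported here. The rule was also applied to the genes above background. A fold against a group with no counts is a bound against a floor of 3 counts over the group.

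The fits were tested on simulated counts with 200 genes changed. Over all genes, the share recovered in the tissue, cell type, pregnancy and pregnant Treg against CD4conv comparisons was 16.7%, 18.2%, 18.2% and 18.2% of 8-fold changes, and 0%, 1.49%, 0% and 1.49% of 4-fold changes (27700, 27466, 27620 and 27616 genes). Above background it was 73.1%, 74.6%, 92.5% and 80.6% of 4-fold changes and 13.4%, 20.9%, 26.9% and 14.9% of 2-fold changes (4714, 4715, 4716 and 4714 genes).

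Alternatives planned before were the 20 and 100 highest genes in place of 50 for the library composition, RLE size factors, no filter on low counts, DESeq2 1.42.0, limma-voom with sample weights, a fit of only the 8 libraries compared, the replicate number as a block, and leaving out each library in turn. Alternatives added after seeing the data were the genes above background, the background share as a covariate, subtraction of the background, and leaving out the 5 libraries with an estimated background share over 30%. Each was compared with the value first reported. A named gene counted as turned in direction only where it passed the threshold in either setting. Total counts per library ran from 1.72 to 15.19 in units of 1e6. Reads made by PCR without molecular identifiers are not independent molecules, so floors cover counting error only. Genes with near-identical copies (Ly6c1 and Ly6c2, Klk1 and its paralogs, Gm21762, and mitochondrially encoded genes with nuclear copies) have uncertain counts because reads can be split between the copies. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.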

Results

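The series profiled RNA of CD4-positive T cells from BALB/c mice that carry a green fluorescent reporter in the Foxp3 gene. Regulatory T cells (Treg, sorted as Foxp3-positive) came from the uterus of non-pregnant mice, from the uterus of pregnant mice and from para-aortic lymph nodes, which drain the uterus, of non-pregnant mice. Conventional CD4-positive T cells (CD4conv, sorted as Foxp3-negative) came from the non-pregnant uterus. The source labels of the pregnant samples give days 6 to 8 of pregnancy, while the titles of 3 of the 4 give a later last day. Each group had 4 libraries, each from a pool of mice. The labels describe both uterine Treg groups as CD25-negative and the lymph node Treg as CD25-positive. The comparisons ask what distinguishes uterine Treg from their conventional neighbours, how they differ from Treg of the draining node, and whether they change in early pregnancy. Total counts were 9.77 ± 1.93 M in CD4conv, 3.52 ± 2.10 M in lymph node Treg, 3.20 ± 1.64 M in uterine Treg and 9.13 ± 5.81 M in pregnant uterine Treg (M, counts in units of 1e6). These and the levels that follow are mean ± SD with n = 4 in each group.

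The libraries held reads in genes that T cells do not use. Together, the 1427 olfactory and vomeronasal receptor genes took between 0.368% and 2.27% of the counts of a library. If such reads fell evenly on all exonic bases they would make up 8.69% of the counts in pregnant uterine Treg replicate 3, the lowest, and 53.6% in pregnant uterine Treg replicate 4, the highest. The estimate exceeded 30% in 5 libraries: lymph node Treg 3, uterine Treg 3 and 5, and pregnant uterine Treg 2 and 4. Gm10800, a gene model whose reads can come from repeats, took 0.952% to 8.96% of the counts. Mitochondrially encoded genes took 0.506% to 0.904%. Genes detected, the mitochondrially encoded share and the share of the 50 highest genes were tested in 4 comparisons by exact two-sided permutation tests, a family of 12. None passed (lowest adjusted p = 0.514, for genes detected in the tissue and cell type comparisons). A single measure that separates its groups fully cannot pass in that family, so the tests do not show that the groups are alike. Genes detected averaged 31916 in uterine Treg, 37729.5 in lymph node Treg and 39814 in CD4conv. The receptor and Gm10800 shares were tested outside the family (lowest unadjusted exact permutation p = 0.0857). Total counts, outside that family, were lower in uterine Treg than in CD4conv (exact permutation p = 0.0286, the smallest that 70 arrangements allow).

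Uterine Treg were set against uterine CD4conv first. Foxp3 (chromosome X, 7573644 to 7595245), the transcription factor that defines the Treg lineage, was at 417 ± 210 CPM in uterine Treg and 1.85 ± 1.52 CPM in CD4conv, a log2 fold change of 7.86 ± 0.97 (SE; adjusted p = 0.000111, edgeR). It was at 559 ± 182 CPM in lymph node Treg and 475 ± 318 CPM in pregnant uterine Treg, and each of the 12 Treg libraries lay above each CD4conv library. The cells were sorted by the Foxp3 reporter, so the sort itself can set the Foxp3 difference between Treg and CD4conv. Other genes of Treg function were higher too. Lrrc32 (chromosome 7, 98489283 to 98502181), which anchors latent TGF-beta on the Treg surface, was at 500 ± 144 against 7.92 CPM (log2 6.10 ± 1.04, adjusted p = 0.00272), with a wide spread in CD4conv. Ctla4 (chromosome 1, 60887000 to 60915832), an inhibitory receptor, was at 1400 ± 568 against 152 ± 81.0 CPM (log2 3.16), and Ikzf2, which encodes Helios, at 434 ± 145 against 56.0 ± 15.04 CPM (log2 2.80).

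Other genes were also higher in uterine Treg. Klrg1, a lectin-like receptor of differentiated lymphocytes, was at 123 ± 54.4 against 10.4 ± 7.94 CPM (log2 3.63). Itgae (chromosome 11, 73090583 to 73147446), the CD103 chain of the integrin that binds E-cadherin, was at 157 ± 36.4 against 15.8 ± 9.78 CPM (log2 3.28). Rln3, which encodes the peptide hormone relaxin 3, was at 32.3 ± 19.2 against 0.616 ± 0.716 CPM (log2 5.74). Vsig10, an immunoglobulin-domain membrane protein, was at 52.0 ± 46.1 against 6.40 ± 2.52 CPM (log2 2.92) and uterine Treg replicate 1 at 121 CPM. Tnfrsf9, the costimulatory receptor 4-1BB, was at 101 ± 25.7 against 14.95 ± 2.65 CPM (log2 2.49). Il2ra, which encodes CD25, was at 96.1 ± 30.6 against 23.2 ± 4.38 CPM and missed the threshold over all genes (log2 1.89 ± 0.58, adjusted p = 0.262, edgeR). The fixed list of tissue residency genes was not called higher: 1 of 15 was higher and 2 lower over all genes, and 1 higher and 4 lower adjusted over the list alone. Its median log2 fold change was -0.31 and it was not called by camera (adjusted p = 0.0892, and adjusted p = 0.504 with an estimated correlation), while fry gave adjusted p = 0.0335 for a lower level. In all, 10 genes were higher and 146 lower in uterine Treg at adjusted p under 0.05 among 30096 tested.

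Of 16 core Treg genes, 5 were higher over all genes and 10 adjusted over the list alone (camera adjusted p = 2.76e-19). With an estimated correlation this list had adjusted p = 0.0961. Of 23 genes of effector and tissue Treg, 1 was higher over all genes (Klrg1) and 2 adjusted over the list alone, with adjusted p = 0.504 with an estimated correlation. Tigit, an inhibitory receptor, was at 71.4 ± 36.1 against 16.9 ± 4.74 CPM, and Rora, a nuclear receptor of tissue lymphocytes, at 818 ± 324 against 217 ± 114 CPM; neither passed over all genes. Helper T cell cytokines and regulators were lower as a list (0 of 16 over all genes, 5 adjusted over the list alone; adjusted p = 0.0172 with an estimated correlation, and 0.218 above background, where 3 of its genes were tested). Its members with the lowest p were Il2, the T cell growth factor, at 2.61 ± 3.68 against 24.0 ± 19.4 CPM, and Tbx21, the Th1 regulator T-bet, at 9.92 ± 6.66 against 52.7 ± 17.6 CPM. Ifng was at 14.3 ± 3.64 against 73.8 ± 22.4 CPM and Cd40lg at 19.6 ± 21.9 against 108 ± 33.2 CPM.

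CD4conv libraries carried high levels of genes that are not typical of CD4-positive T cells. Ly6c2 (chromosome 15, 75108158 to 75111970) and Ly6c1, which encode near-identical surface proteins of monocytes, plasmacytoid dendritic cells and some T cells, were at 454 ± 215 and 544 ± 249 CPM in CD4conv and at 2.70 ± 3.27 and 8.17 ± 8.57 CPM in uterine Treg (log2 -8.09 and -6.75). Rnase6, a secreted ribonuclease, was at 256 ± 86.1 against 3.68 ± 4.27 CPM (log2 -6.86), and Mgl2, a lectin of macrophages and dendritic cells, at 63.3 ± 63.6 against 0.770 ± 1.19 CPM (log2 -7.01). Cox6a2, a cytochrome oxidase subunit, was at 143 ± 68.4 CPM in CD4conv and had no count in the 4 uterine Treg libraries, at least 609-fold lower against a floor of 0.234 CPM over the group. Gm21762, a predicted gene, was at 34.6 ± 15.2 CPM and likewise at 0, at least 148-fold lower. Smim5, a small membrane protein, was at 54.7 ± 28.5 against 0.371 ± 0.742 CPM and Lefty1, a TGF-beta family antagonist, at 36.8 ± 12.4 against 0.283 ± 0.347 CPM.

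Of 13 marker lists of other cells, 4 were called lower in uterine Treg than in CD4conv over all genes. Of 12 NK cell markers, 2 were lower over all genes and 6 adjusted over the list alone (adjusted p = 0.000927 with an estimated correlation). These were Tyrobp (774 ± 418 against 9.40 ± 6.24 CPM, log2 -6.72) and Fcer1g (226 ± 189 against 10.4 ± 5.72 CPM, log2 -5.09), adaptors that myeloid cells also use. Cd7 was at 157 ± 47.9 against 24.0 ± 11.03 CPM and Ncr1, an NK receptor, at 22.3 ± 8.70 against 3.17 ± 3.48 CPM. Of 15 macrophage and dendritic cell markers, 7 were lower over all genes and 14 adjusted over the list alone (adjusted p = 0.0720 with an estimated correlation). The MHC class II genes Cd74 (5247 ± 3787 against 133 ± 71.1 CPM, log2 -5.87), H2-Aa (993 ± 785 against 21.8 ± 13.1 CPM) and H2-Ab1 (1348 ± 1024 against 48.6 ± 17.7 CPM) were among them, with Cd68 at 202 ± 131 against 4.86 ± 3.34 CPM. Macrophage genes were uneven within CD4conv: Apoe was at 418, 3588, 4652 and 22.3 CPM and C1qb at 32.7, 278, 343 and 6.39 CPM in replicates 1, 2, 3 and 5. The mean log2 CPM (plus 1) of macrophage and dendritic cell markers was 4.75 in CD4conv 5, below 5.15 in uterine Treg 5. Of 7 CD8 and gamma delta T cell markers, Cd8b1 (250 ± 87.7 against 16.6 ± 7.49 CPM, log2 -4.33) and Cd8a (36.9 ± 14.2 against 2.46 ± 1.86 CPM) were lower, 2 also adjusted over the list alone (adjusted p = 0.128 with an estimated correlation). Of 12 B cell markers, 1 was lower over all genes and 2 adjusted over the list alone (adjusted p = 0.366 with an estimated correlation). The other 9 lists were not called: the median log2 fold change was 1.17 for fibroblast (11 of 12 positive), 0.43 for decidua, 0.30 for trophoblast and embryo, 0.11 for neutrophil, 0.05 for mast cell and ILC2, -0.02 for smooth muscle, -0.11 for erythroid, -0.16 for epithelial and -0.18 for endothelial markers. For neutrophil, smooth muscle, erythroid and endothelial markers the camera direction was opposite to the median.

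**Figure D1:**
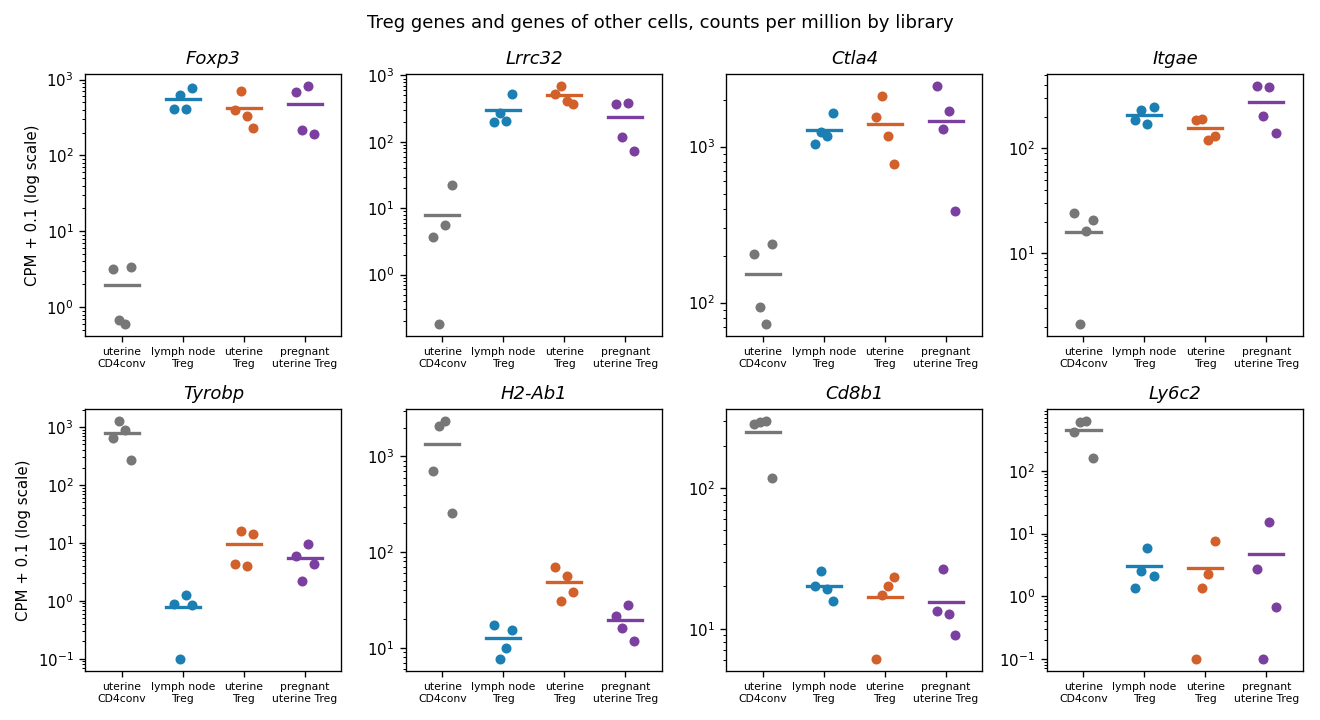
CPM plus 0.1 on a log scale for 4 Treg genes (Foxp3, Lrrc32, Ctla4, Itgae) and 4 genes associated with other cells (Tyrobp, H2-Ab1, Cd8b1, Ly6c2); each point is a library and each bar the arithmetic mean of 4. Foxp3 lies between 0.503 and 3.26 CPM in CD4conv and between 192 and 814 CPM in the 12 Treg libraries.

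Of the other lists called with the preset correlation, interferon response was lower (1 of 18 over all genes, Bst2, and 8 adjusted over the list alone), as were cholesterol synthesis (0 of 16, and 0 adjusted over the list alone) and mitochondrially encoded genes (0 of 11, and 3 adjusted over the list alone). NF-kB response was higher (0 of 13, and 0 adjusted over the list alone). With an estimated correlation the adjusted p of these 4 lists was 0.392, 0.525, 0.703 and 0.868. With the preset correlation, NF-kB response had adjusted p = 0.116 and 0.226 without CD4conv 1 and 5 and 0.196 and 0.684 without uterine Treg 1 and 2, cholesterol synthesis 0.0813 without uterine Treg 3, and mitochondrially encoded genes 0.0800 without CD4conv 2 and 0.10 without uterine Treg 3. Effector and tissue Treg genes had 0.0561 without uterine Treg 2 and B cell markers 0.0843 without CD4conv 3. Leaving out 1 library took the count of higher genes from 10 to 4, 3, 3 and 5 (CD4conv 1, 2, 3 and 5) or to 3, 3 and 5 (uterine Treg 1, 2 and 3). It took that of lower genes from 146 to 80 and 69 (CD4conv 2 and 3) or to 79 and 90 (uterine Treg 1 and 3). Foxp3, Lrrc32 and Rln3 stayed past the threshold in 8 of 8 such fits, Itgae in 3, Klrg1 and Vsig10 in 2, Ctla4 and Ikzf2 in 1 and Tnfrsf9 in 0. Cd8a was past it in 7 (not without CD4conv 2). The groups were sequenced in different batches. In pregnant uterine Treg against CD4conv, both of batch 1, none of these 4 lists was called over all genes: the median log2 fold change was -0.07 for interferon response (camera adjusted p = 0.992), -0.31 for cholesterol synthesis (adjusted p = 0.212), -0.43 for mitochondrially encoded genes (adjusted p = 0.0929) and 0.51 for NF-kB response (adjusted p = 0.332). Above background, NF-kB response was called higher in pregnant uterine Treg than in CD4conv (camera adjusted p = 0.000333, and adjusted p = 0.116 with an estimated correlation). Between pregnant and non-pregnant uterine Treg the interferon list had a median of 1.28, against -1.39 between uterine Treg and CD4conv, so for this list batch and cell type cannot be told apart. The 146 lower genes had a median of 0.33 between these uterine Treg groups.

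Pregnant uterine Treg were sequenced in the same batch as CD4conv, and that comparison called 10 genes higher and 120 lower. Foxp3 was higher by log2 8.24 ± 0.98 (adjusted p = 7.78e-05, edgeR), Lrrc32 by 5.26 (234 ± 163 CPM), Itgae by 4.30 (279 ± 126 CPM), Ctla4 by 3.36 (1456 ± 856 CPM) and Tnfrsf9 by 3.18 (135 ± 60.3 CPM). Slpi, a secreted protease inhibitor, was at 1.20 ± 1.38 against 201 ± 113 CPM in CD4conv (log2 -7.56), and Klk1, tissue kallikrein, at 4.69 ± 3.74 against 641 ± 260 CPM (log2 -7.40). Cox6a2, Lefty1 and Gm21762 were at 0.174 ± 0.209, 0.157 ± 0.313 and 0.0772 ± 0.154 CPM in pregnant uterine Treg. The core Treg list had 5 of 16 genes higher over all genes and 10 adjusted over the list alone (adjusted p = 0.125 with an estimated correlation). NK cell markers (2 of 12, and 3 adjusted over the list alone), macrophage and dendritic cell markers (6 of 15, and 14 adjusted over the list alone) and helper cytokines (0 of 16, and 6 adjusted over the list alone) were lower, with adjusted p = 0.00321, 0.0203 and 0.0146 with an estimated correlation. Above background, where the helper list has 3 tested genes, that adjusted p was 0.0220, 0.116 and 0.116, so the last 2 lists did not pass. Also called over all genes were effector and tissue Treg (median log2 fold change 0.99), cell cycle (0.67), endothelial (1.16) and smooth muscle (1.20) lists as higher. Lists of tissue residency (-0.35), naive and recirculation (-0.17), immediate early (-0.41) and CD8 and gamma delta T cell (-2.06) genes were called lower. With an estimated correlation none of these 8 passed (lowest adjusted p = 0.0933, CD8 and gamma delta T cell). With the preset correlation, adjusted p without pregnant uterine Treg 3 was 0.191 for cell cycle, 0.371 for endothelial and 0.0694 for smooth muscle lists. Without pregnant uterine Treg 2 and 4 it was 0.147 and 0.0854 for tissue residency, 0.406 and 0.340 for naive and recirculation, and 0.272 and 0.527 for immediate early genes. It was 0.0865 and 0.106 for naive and recirculation genes without CD4conv 1 and 2, and 0.0895 for immediate early genes without CD4conv 2. Both comparisons use the same CD4conv libraries. Without CD4conv 1, CD4conv 3, or pregnant uterine Treg 1, 3 or 4 the higher count was 5, 2, 6, 5 or 20. Without CD4conv 3 or pregnant uterine Treg 2 the lower count was 70 or 76. Klk1 was past the threshold in 4 of 8 such fits (not without CD4conv 2 or pregnant uterine Treg 2, 3 or 4). Ctla4 was past it in 2 (not without any CD4conv library or pregnant uterine Treg 1 or 3), and Lrrc32 and Tnfrsf9 in 7 (not without CD4conv 3).

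Among the 4723 genes above background, a set chosen after seeing the data, 147 were higher and 141 lower in uterine Treg than in CD4conv, and 194 and 202 in pregnant uterine Treg. Of 15 core Treg genes, 11 were higher in uterine Treg and 14 adjusted over the list alone (adjusted p = 0.00496 with an estimated correlation), with Il2ra now past the threshold (log2 2.13 ± 0.25, adjusted p = 3.65e-05, edgeR). Of 16 effector and tissue Treg genes, 5 were higher and 12 adjusted over the list alone (adjusted p = 0.0267 with an estimated correlation): Tigit (log2 2.15), Rora (log2 2.00), Klrg1 (log2 3.65), Irf4, a transcription factor of effector Treg, at 184 ± 70.7 against 76.6 ± 18.3 CPM, and Nfil3, a transcription factor of lymphocytes named after its values were seen. Areg, the epidermal growth factor family member amphiregulin, was at 49.1 ± 28.1 against 6.26 ± 1.39 CPM (log2 2.98 ± 0.57, adjusted p = 0.00291, edgeR). Over all genes it did not pass (adjusted p = 0.152, edgeR). Gata3 (204 ± 93.9 against 119 ± 34.2 CPM), Il1rl1 (68.3 ± 29.1 against 36.1 ± 11.2 CPM) and Il10 (17.3 ± 9.65 against 7.07 ± 3.33 CPM) did not pass in uterine Treg. In pregnant uterine Treg against CD4conv, Il1rl1, the IL-33 receptor, was higher (152 ± 62.9 CPM, log2 2.22, adjusted p = 0.000365, edgeR), as was Il10 (26.1 ± 8.81 CPM, log2 2.22). Neither passed over all genes. Ccr7 (798 ± 278 against 554 ± 280 CPM) and, over all genes, Mki67 (55.7 ± 29.7 against 32.5 ± 12.6 CPM) did not pass in uterine Treg. Irf4 was past the threshold in 4 of 8 fits with 1 library left out (not without CD4conv 1 or 2 or uterine Treg 1 or 3). Leaving out CD4conv 1, 2 or 3 lowered the count of genes higher in uterine Treg to 89, 95 or 91. With the replicate number as a block, 59 were higher and 63 lower in uterine Treg. In pregnant uterine Treg, leaving out CD4conv 1 or 3 lowered the higher count to 116 or 115. The fit of only the 8 libraries compared gave 65 higher and 99 lower there.

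Uterine Treg were next compared with Treg of the draining lymph nodes, both from batch 2. The labels give the uterine Treg as CD25-negative and the lymph node Treg as CD25-positive. Tissue and CD25 status therefore cannot be told apart for any gene or list in this comparison. Over all 30096 genes, 0 were higher and 0 lower by edgeR, with 905 at unadjusted p under 0.05; DESeq2 called 12 higher and 16 lower, and limma-voom 1 and 2. Among genes above background, chosen after seeing the data, 44 were higher and 17 lower in uterine Treg. Itgb1 (chromosome 8, 128685654 to 128733200), the integrin beta 1 chain, was at 1389 ± 461 CPM in uterine and 338 ± 101 CPM in lymph node Treg (log2 2.16 ± 0.34, adjusted p = 0.00337, edgeR). S100a4 (chromosome 3, 90603771 to 90606045) and S100a6, calcium-binding proteins of activated and memory T cells, were at 35.2 ± 15.1 against 4.39 ± 2.39 CPM (log2 3.12 ± 0.56) and 244 ± 100.2 against 49.0 ± 19.9 CPM (log2 2.44). Cxcr3 (chromosome X, 101731535 to 101734269), a chemokine receptor for entry into inflamed tissue, was at 139 ± 118 against 26.8 ± 5.23 CPM (log2 2.46 ± 0.39).

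Further genes higher in uterine Treg were Cdc25b, a cell cycle phosphatase, at 313 ± 112 against 63.6 ± 7.77 CPM (log2 2.42), Lgals3, galectin 3, at 31.6 ± 7.10 against 6.72 ± 1.30 CPM (log2 2.37). Egr1, an immediate early transcription factor, was at 471 ± 306 against 113 ± 30.3 CPM (log2 2.31), and Myo1f, an unconventional myosin of immune cells, at 256 ± 33.5 against 63.2 ± 18.1 CPM (log2 2.19). Lower in uterine Treg were Ccr7 (chromosome 11, 99144196 to 99155077), the receptor that guides T cells to lymph nodes, at 798 ± 278 against 2835 ± 1385 CPM (log2 -1.69 ± 0.37, adjusted p = 0.0314). So were Gpr83, an orphan receptor of Treg, at 33.0 ± 16.7 against 204 ± 66.9 CPM (log2 -2.46), Penk, which encodes proenkephalin, at 18.6 ± 11.5 against 106 ± 9.19 CPM (log2 -2.29). Ccr8, a chemokine receptor, was at 24.0 ± 6.23 against 113 ± 28.01 CPM (log2 -2.04). Eno3, muscle enolase, was at 3.65 ± 3.76 against 79.8 ± 26.8 CPM (log2 -4.21), Chchd10, a mitochondrial protein, at 14.9 ± 8.84 against 73.0 ± 31.7 CPM (log2 -2.05). Dusp2, a MAP kinase phosphatase, was at 106 ± 53.0 against 415 ± 80.3 CPM (log2 -1.87), and Ctsw, cathepsin W, at 35.7 ± 16.6 against 123 ± 16.5 CPM (log2 -1.67). Foxp3 (log2 -0.32 ± 0.42), Gata3 (log2 0.15), Areg (log2 1.25 ± 0.54, adjusted p = 0.393) and Il10 (log2 -1.44 ± 0.54, adjusted p = 0.275) did not pass, nor did Mki67 over all genes (log2 0.55 ± 0.53).

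Of 15 core Treg genes, 3 were lower in uterine Treg (6 lower and 1 higher adjusted over the list alone; adjusted p = 0.633 with an estimated correlation). They were Gpr83, Il2ra (96.1 ± 30.6 against 295 ± 62.1 CPM, log2 -1.48 ± 0.25, adjusted p = 0.00425) and Tnfrsf9 (101 ± 25.7 against 309 ± 53.2 CPM, log2 -1.41). Il2ra encodes CD25, the marker for which the labels give the lymph node Treg as positive and the uterine Treg as negative, so the sort gate can set its difference. Izumo1r, folate receptor 4, was at 212 ± 103 against 543 ± 201 CPM and did not pass (adjusted p = 0.143). Of 16 effector and tissue Treg genes, Rora was higher (818 ± 324 against 280 ± 157 CPM, log2 1.68) and Ccr8 lower, with 7 higher and 2 lower adjusted over the list alone (adjusted p = 0.633 with an estimated correlation). Il1rl1 was at 68.3 ± 29.1 against 32.5 ± 11.4 CPM and Irf4 at 184 ± 70.7 against 99.2 ± 13.5 CPM, and neither passed. The camera adjusted p of the core list was 0.00833, and 0.120 without uterine Treg 5. That of the effector and tissue list was 0.0386, and 0.138 without lymph node Treg 1 and 0.123, 0.112 and 0.113 without uterine Treg 1, 2 and 3.

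Some marker lists of other cells were called higher in uterine than in lymph node Treg. Of 11 macrophage and dendritic cell markers above background, 0 passed and 4 did so adjusted over the list alone (camera adjusted p = 0.00163, and adjusted p = 0.633 with an estimated correlation). H2-Ab1 was at 48.6 ± 17.7 against 12.5 ± 4.45 CPM, C1qb, a complement gene of macrophages, at 13.2 ± 12.3 against 0.185 ± 0.275 CPM, and Apoe at 191 ± 228 against 8.65 ± 2.76 CPM, with uterine Treg replicate 5 at 532 CPM. Of 5 NK cell markers, Tyrobp (9.40 ± 6.24 against 0.679 ± 0.488 CPM, log2 3.90) and Fcer1g (10.4 ± 5.72 against 0.494 ± 0.252 CPM, log2 4.72) were higher, 2 also adjusted over the list alone (adjusted p = 0.414 with an estimated correlation). The background filter used the mean over all 16 libraries. CD4conv held the highest levels of Tyrobp, Fcer1g and C1qb (774, 226 and 165 CPM), so that group can have brought them into this gene set. Their levels in lymph node Treg rest on few counts. Over all genes, lists of macrophage, fibroblast, epithelial, endothelial and erythroid markers were called higher and core Treg genes lower, with 0 members past the threshold over all genes in each. Adjusted over the list alone, 3, 6, 2, 0 and 2 of these markers were higher and 3 core genes lower. With an estimated correlation adjusted p was 0.745 for the 5 marker lists and 0.861 for core Treg genes. Without uterine Treg 5, camera adjusted p was 0.156 for fibroblast, epithelial, endothelial and erythroid markers and 0.894 for core Treg genes. It was 0.114 for endothelial and for erythroid markers and 0.655 for core Treg genes without lymph node Treg 1, 0.106 for core Treg genes without lymph node Treg 5, and 0.212 for erythroid markers and 0.528 for core Treg genes without uterine Treg 3. Of the 8 marker lists not called over all genes, the median log2 fold change was 0.90 for neutrophil, 0.39 for decidua, 0.29 for mast cell and ILC2 and 0.23 for trophoblast and embryo markers. It was -0.48 for B cell, -0.49 for CD8 and gamma delta T cell, -0.29 for smooth muscle and -0.27 for NK cell markers. The mean was above 0 for the last 2 lists, and the camera direction of NK cell markers was higher. Above background, NK cell markers had 0.0864 without lymph node Treg 1 and 0.0678 without uterine Treg 2.

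**Figure D2:**
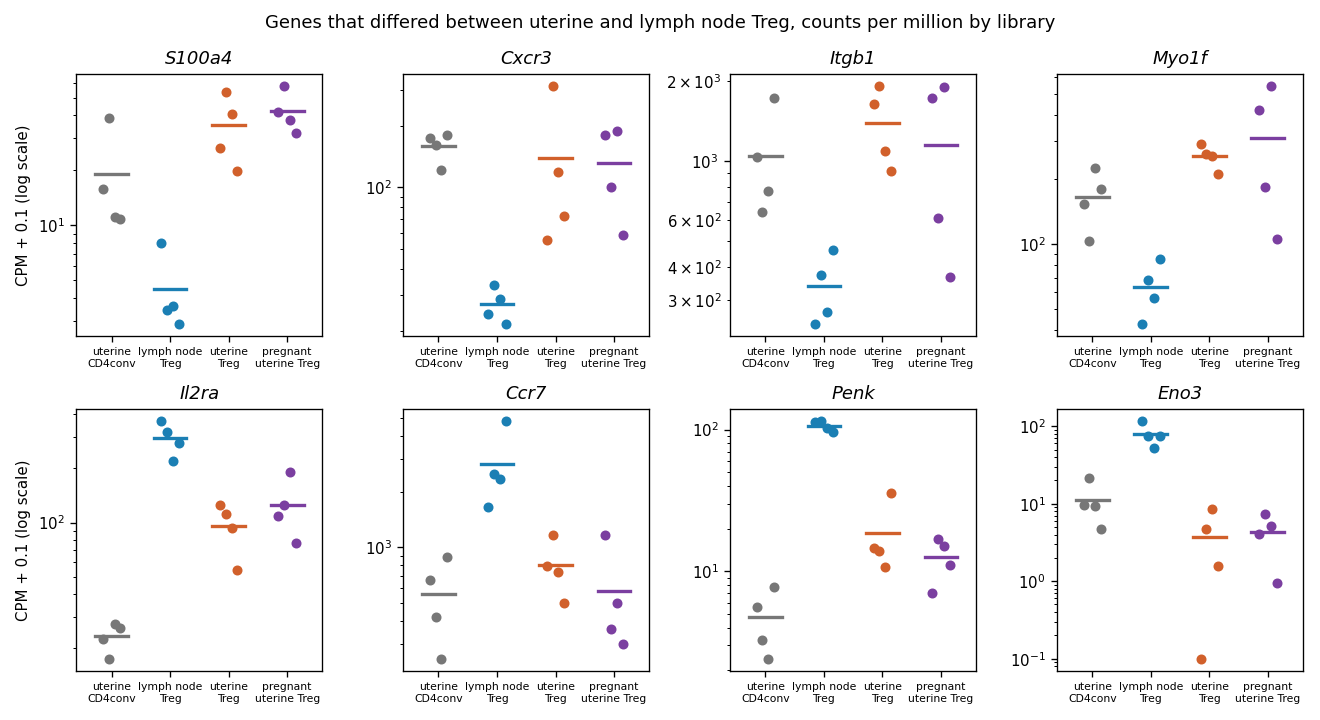
CPM plus 0.1 on a log scale for 4 genes higher (S100a4, Cxcr3, Itgb1, Myo1f) and 4 lower (Il2ra, Ccr7, Penk, Eno3) in uterine than in lymph node Treg among genes above background; each point is a library and each bar the arithmetic mean of 4. For S100a4 the 4 uterine Treg libraries lie between 19.8 and 53.6 CPM and the 4 lymph node libraries between 2.78 and 7.94 CPM.

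In this gene set 512 genes had unadjusted p under 0.05, DESeq2 called 90 higher and 44 lower, and limma-voom 157 and 90. Leaving out lymph node Treg 1, 2, 3 or 5 gave 22, 15, 16 or 25 higher and 9, 4, 5 or 7 lower. Leaving out uterine Treg 1, 2 or 3 gave 21, 16 or 20 higher and 7, 7 or 6 lower. Leaving out the 5 libraries with over 30% background, which include uterine Treg 5, gave 12 and 5. S100a4, S100a6, Cxcr3, Cdc25b, Myo1f, Itgb1, Il2ra, Tnfrsf9 and Dusp2 stayed past the threshold without any 1 library. Eno3 did so in 5 of 8 fits, Tyrobp in 6, Lgals3, Ctsw, Rora and Fcer1g in 3, Egr1 and Ccr8 in 2, Ccr7, Penk and Chchd10 in 1 and Gpr83 in 0.

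Pregnant and non-pregnant uterine Treg were compared last. Genes of the interferon response had higher means in pregnant uterine Treg, while no gene passed the threshold. Rtp4, an interferon-induced chaperone (chromosome 16, 23520291 to 23614222), was at 109 ± 38.4 against 37.1 ± 14.0 CPM (log2 1.59 ± 0.35, adjusted p = 0.316, edgeR, genes above background). Ifit3 (chromosome 19, 34583531 to 34588731) was at 33.0 ± 19.0 against 5.12 ± 2.02 CPM (log2 2.77 ± 0.68), and Isg15 (chromosome 4, 156199424 to 156200818), a ubiquitin-like modifier, at 31.8 ± 11.4 against 10.2 ± 1.13 CPM (log2 1.70 ± 0.54). Over all genes, 18 of 18 members of the interferon response list had a positive log2 fold change (median 1.28), 0 passed and 3 did so adjusted over the list alone (camera adjusted p = 2.98e-06, and adjusted p = 0.880 with an estimated correlation). In genes above background, chosen after seeing the data, 14 of 14 members were positive (median 1.13), 0 passed and 9 did so adjusted over the list alone. That list was past the threshold with the preset correlation (adjusted p = 5.06e-11), with an estimated correlation (adjusted p = 0.0297) and with fry (adjusted p = 0.00578).

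Over all genes, 0 were higher and 0 lower in pregnant uterine Treg by edgeR, with 822 at unadjusted p under 0.05; DESeq2 called 5 higher and 8 lower, and limma-voom 0 and 0. Above background the counts were 0 and 0 with 301 at unadjusted p under 0.05, DESeq2 called 5 and 2, and limma-voom 0 and 0. This comparison equals the difference between the effects of the preceding Treg against CD4conv comparisons, for which edgeR on all 16 libraries thus called no gene. Il1rl1 (chromosome 1, 40429570 to 40465415) was at 152 ± 62.9 CPM in pregnant and 68.3 ± 29.1 CPM in non-pregnant uterine Treg (log2 1.24 ± 0.33, adjusted p = 0.652, genes above background). In the same genes Foxp3 had a log2 fold change of 0.20 ± 0.42, Il2ra (125 ± 47.9 CPM in pregnant uterine Treg) of 0.49 ± 0.24, Areg (37.8 ± 28.1 CPM) of -0.39 ± 0.53. Gata3 (173 ± 74.5 CPM) had -0.15 ± 0.25, Il10 0.85 ± 0.53 and Ccr7 (580 ± 397 CPM) -0.42 ± 0.37. Over all genes Mki67 (76.9 ± 15.1 CPM) had 0.53 ± 0.53.

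Mitochondrially encoded genes above background had positive fold changes in 10 of 10 cases, with a median log2 fold change of 0.20. Of these, 0 passed the threshold and 3 did so adjusted over the list alone (camera adjusted p = 0.000375, and adjusted p = 0.550 with an estimated correlation). The share of counts in mitochondrially encoded genes was 0.730% in pregnant and 0.689% in non-pregnant uterine Treg (unadjusted exact permutation p = 0.686). The cytochrome oxidase genes mt-Co3 and mt-Co2 were at 32.3 ± 14.7 against 11.2 ± 3.44 CPM and 28.3 ± 9.89 against 10.2 ± 3.31 CPM, and the ATP synthase gene mt-Atp6 at 31.9 ± 13.1 against 11.5 ± 2.44 CPM. The more abundant mt-Nd1 was at 1386 ± 310 against 1282 ± 227 CPM. Across the batches, mt-Co3 was at 56.0 ± 13.0 CPM in CD4conv of batch 1 and 16.1 ± 4.53 CPM in lymph node Treg of batch 2. Isg15 was at 32.5 ± 22.9 CPM in CD4conv and 14.3 ± 6.78 CPM in lymph node Treg, and Rtp4 at 46.7 ± 16.9 and 45.4 ± 12.8 CPM. Over all genes, endothelial and smooth muscle markers were called higher with the preset correlation (0 of 12 and 0 of 6 past the threshold, 0 and 0 adjusted over the list alone; adjusted p = 0.972 and 0.880 with an estimated correlation). Without non-pregnant uterine Treg 1, 2 or 3 or pregnant uterine Treg 3 or 4 the endothelial markers had camera adjusted p = 0.0636, 0.0947, 0.107, 0.501 or 0.0942. Without non-pregnant uterine Treg 1 or 2 or pregnant uterine Treg 1, 3 or 4 the smooth muscle markers had 0.0620, 0.256, 0.205, 0.517 or 0.174. The median log2 fold changes of other lists that pregnancy could bring were 0.57 for decidual, 0.05 for trophoblast and embryo, -0.48 for fibroblast and -0.56 for epithelial markers, and none of these lists was called.

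**Figure D3:**
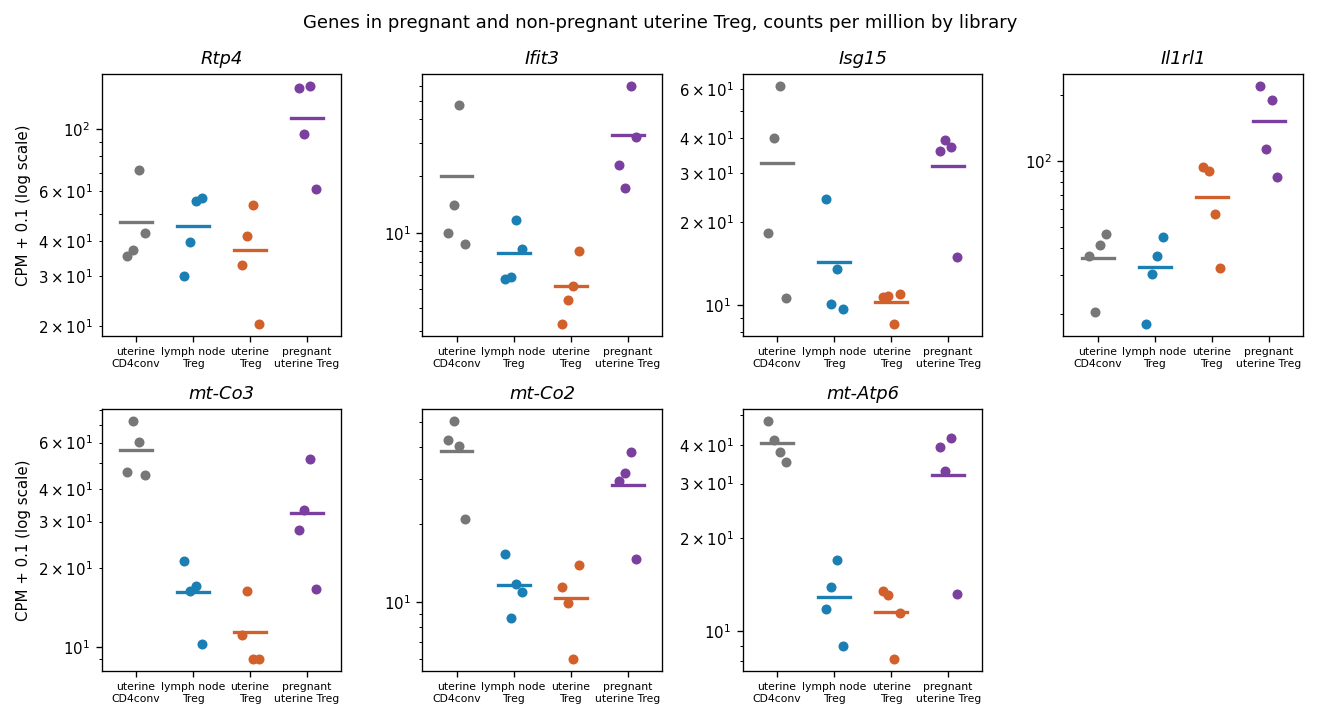
CPM plus 0.1 on a log scale for 3 interferon response genes (Rtp4, Ifit3, Isg15), Il1rl1 and 3 mitochondrially encoded genes; each point is a library and each bar the arithmetic mean of 4. No gene shown passed the threshold between pregnant and non-pregnant uterine Treg; for Isg15 the 4 pregnant libraries lie between 14.8 and 39.3 CPM and the 4 non-pregnant ones between 8.49 and 10.9 CPM.

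Pregnancy and sequencing batch cannot be told apart in this comparison. The 5 libraries with an estimated background over 30% include 2 of the 4 in each group, and without all 5, a fit added after seeing the data, edgeR called 3 genes higher and 1 lower over all genes and 1 and 0 in genes above background.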

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

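No explanation was tested for the values in this part. Within each group of 4 libraries, the gap between the highest or lowest library and its nearest neighbour was compared with the range of the group; 328 such groups were tested, and 22 values stood apart by more than the Dixon limit for 4 values. Chance sets apart a library in about 1 in 20 groups. CD4conv replicate 2 had 33707 genes detected, fewer than the other CD4conv libraries, and the 50 highest genes of lymph node Treg replicate 1 took 23.3% of its counts, more than in the other lymph node libraries.

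In CD4conv, replicate 3 was the highest for Ccr2 (772 CPM) and Ifit3 (47.4 CPM), and replicate 5 the lowest for Cd8b1 (119 CPM). In lymph node Treg, replicate 1 was the highest for Izumo1r (842 CPM), S100a4 (7.94 CPM) and Cox6a2 (0.318 CPM), and replicate 5 the highest for Nfkb2 (312 CPM). In non-pregnant uterine Treg, replicate 5 was the highest for Apoe (532 CPM), Klk1 (161 CPM), Penk (35.6 CPM) and Smim5 (1.48 CPM), replicate 3 the highest for Il2 (8.06 CPM) and Mgl2 (2.55 CPM) and the lowest for Isg15 (8.49 CPM), and replicate 1 the highest for Vsig10 (121 CPM). In pregnant uterine Treg, replicate 4 was the highest for Vsig10 (78.3 CPM) and the lowest for Isg15 (14.8 CPM), replicate 3 the highest for Apoe (97.4 CPM), replicate 2 the highest for Lefty1 (0.627 CPM) and replicate 1 the highest for Gm21762 (0.309 CPM). Cox6a2, Smim5, Lefty1 and Gm21762 had no count in the other libraries of these groups, so any count there stands apart. A level of 3 counts equals 0.476, 1.48, 0.627 and 0.231 CPM in the libraries named for them, in that order.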

How the results depend on the processing

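The fits on genes above background, without libraries over 30% background, with the background as a covariate and with the background subtracted were chosen after seeing the data; the other settings were planned. No named gene changed direction among those that passed in either setting. The direction of gene lists and the balance of gene counts were not checked in this way. Of the fold changes of named genes under the alternatives, 1482 over all genes and 1713 in genes above background kept their side of the threshold, 95 and 44 passed it only under the alternative, and 85 and 159 no longer passed it. The cause of the changes below was not tested, except that fits of fewer libraries hold less information. Counts are given as higher and lower.

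Over all genes, DESeq2 called 12 and 16 in the tissue comparison, 49 and 292 in the cell type comparison, 5 and 8 in the pregnancy comparison and 56 and 274 in pregnant Treg against CD4conv. Limma-voom called 1 and 2 in the tissue comparison, 16 and 250 in the cell type comparison and 17 higher in pregnant Treg against CD4conv. Fitting only the 8 libraries compared gave 2 and 76 in pregnant Treg against CD4conv. Without libraries over 30% background the counts were 1 and 1 (tissue), 108 and 319 (cell type) and 3 and 1 (pregnancy). In pregnant Treg against CD4conv they were 125 and 105, where the fit of all 16 libraries gave 10 and 120. With background as a covariate they were 11 and 11 (tissue), 96 and 255 (cell type) and 72 and 275 (pregnant Treg against CD4conv). Leaving out 1 library gave 3 to 10 and 69 to 165 in the cell type comparison and 2 to 20 and 70 to 155 in pregnant Treg against CD4conv. RLE size factors and no filter on low counts left each count within 1.5 times its value.

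In genes above background, DESeq2 called 90 and 44 (tissue), 232 lower (cell type), 5 and 2 (pregnancy) and 292 and 326 (pregnant Treg against CD4conv), and limma-voom 157 and 90 (tissue), 290 and 222 (cell type) and 392 and 393 (pregnant Treg against CD4conv). Only the 8 libraries compared gave 79 and 36 (tissue) and 65 and 99 (pregnant Treg against CD4conv). Without libraries over 30% background the counts were 12 and 5 (tissue), 1 higher (pregnancy) and 111 lower (pregnant Treg against CD4conv). Subtracting the background gave 11 lower (tissue) and 129 and 118 (pregnant Treg against CD4conv). Leaving out 1 library gave 15 to 46 and 4 to 16 (tissue), 89 to 167 higher (cell type), and 115 to 217 and 122 to 256 (pregnant Treg against CD4conv).

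Lists called over all genes numbered 6 (tissue), 11 (cell type), 3 (pregnancy) and 12 (pregnant Treg against CD4conv); an estimated correlation left 0, 2, 0 and 3 and fry called 0, 7, 0 and 4. In genes above background they numbered 4, 10, 2 and 8, with 0, 3, 1 and 3 under an estimated correlation, and fry called 0 in the tissue and 1 in the pregnancy comparison. Without libraries over 30% background 3 lists were called over all genes and 1 above background in the tissue comparison. Leaving out 1 library gave 1 to 11 (tissue) and 1 to 7 (pregnancy) lists over all genes, and 2 to 4 (tissue) and 5 to 11 (cell type) above background.

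The labels do not say whether equal replicate numbers share animals among the non-pregnant groups. Pools of pregnant and non-pregnant mice cannot share animals, so equal numbers give no pairing by animal in comparisons with pregnant uterine Treg. No pair of groups had correlations over 0.1 for every shared number. Correlations between equally numbered libraries of pregnant uterine Treg and CD4conv were 0.0990, 0.108 and 0.102 in genes above background but -0.070, -0.182 and -0.034 over all genes. For uterine Treg and CD4conv they were -0.027, 0.223, 0.110 and 0.186 over all genes and 0.124, 0.091, 0.062 and -0.209 above background (replicates 1, 2, 3 and 5). With the replicate number as a block, 1 gene was higher in pregnancy and 4 in pregnant Treg against CD4conv over all genes. Above background 28 were lower in the tissue comparison and 59 higher and 63 lower in the cell type comparison, and 3 lists over all genes and 2 above background were called in the tissue comparison.

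In simulated data the fits over all genes recovered 0% of 2-fold changes and at most 18.2% of 8-fold changes, so a count of 0 does not exclude changes of that size.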

Other observations

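Set before their results were seen were the counts of genes over all splits with all genes tested, the test of the pregnancy genes across batches, planned for called genes, and that of RNA from decidua, epithelium or embryo. As no gene was called, the former was run on the 301 genes at unadjusted p under 0.05, a set chosen after the result was seen. Chosen then too were the split counts for lists and for genes above background, and the tests of the interferon list across splits and batches. So were the tests of reads in silent genes, of batch for the cell type genes and of plasmacytoid dendritic cells.

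Above background, 5 of 13 genes of the NF-kB response were higher in uterine Treg than in CD4conv and 7 adjusted over the list alone (adjusted p = 0.0680 with an estimated correlation). They included Traf1, a signalling adaptor of TNF receptors, at 638 ± 283 against 194 ± 55.6 CPM (log2 1.78) and Nfkb2 at 241 ± 109 against 98.3 ± 20.8 CPM (log2 1.35). In pregnant uterine Treg against CD4conv, both of batch 1, 3 of the 13 were higher and 4 adjusted over the list alone (adjusted p = 0.116 with an estimated correlation). Of 8 chemokine receptors, Cxcr3 and Ccr2 were higher and Ccr8 lower in uterine than in lymph node Treg, the same numbers as adjusted over the list alone (adjusted p = 0.633 with an estimated correlation). Ccr2 was at 189 ± 70.1 against 72.2 ± 6.97 CPM (adjusted p = 0.0360, edgeR), past the threshold in 1 of 8 fits with 1 library left out (the fit without uterine Treg 5). Ccr4 at 52.9 ± 12.3 against 34.2 ± 8.16 CPM did not pass.

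Each comparison was repeated for all 35 splits of its 8 libraries, fitted on those 8 alone. For the number of genes, only the real split, 1 of 35, reached the count in the cell type comparison (148 genes, highest other 1, and above background 212, highest other 1). The same held for pregnant Treg against CD4conv (78, highest other 1, and above background 164, highest other 1) and for the tissue comparison above background (115, highest other 1). These counts argue against chance. However, 1 of 35 is the smallest share possible and was not adjusted for the number of split tests. The splits decide nothing where the real count was 0, which 35 of 35 reach in any case: the tissue comparison over all genes (highest other 0) and pregnancy (highest other 2735, and 41 above background). The split with 41 genes set pregnant uterine Treg 1 and 3 and non-pregnant 1 and 2 against the rest, which is lower against higher estimated background, a structure of the samples. For the number of lists over all genes chance cannot be excluded in the tissue (3, highest other 14; 20 of 35), cell type (11, highest other 16; 9), pregnancy (4, highest other 16; 23) or pregnant Treg against CD4conv (12, highest other 19; 11) comparison. Nor can it above background (3, highest other 4, 4 of 35; 10, highest other 10, 3; 2, highest other 5, 19; 8, highest other 8, 3).

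The interferon response list was called higher in pregnant than in non-pregnant uterine Treg, but with an estimated correlation only above background (adjusted p = 0.0297) and not over all genes (adjusted p = 0.880). Chance cannot be excluded: it was picked among 21 lists, and above background any list reached its median log2 fold change in 26 of 35 splits (1.12, highest other 6.92) and its camera p in 2 of 35 (2.57e-14, lowest other 2.56e-18), against 30 and 5 over all genes. The median is not scaled by a list's spread, so variable lists can reach it in many splits. The interferon list alone reached its own median in 1 of 35 splits above background (highest other 0.724) and in 2 of 35 over all genes (1.23, highest other 1.35). As it was picked from the real split, these counts do not exclude chance. The batch stays open: in CD4conv of batch 1 minus lymph node Treg of batch 2 the list's median was 0.96, or 0.77 without plasmacytoid dendritic cell markers (adjusted p = 0.289 for the list with an estimated correlation). The 301 genes went the same way there in 53.8% of cases, against 49.3% over all genes above background, and batch and pregnancy cannot be told apart. For RNA of decidual stroma, epithelium or embryo, the rule set before counted a median at or below 0 in any of 4 marker lists against this source. Epithelial (-0.56) and fibroblast (-0.48) markers met it, while decidual (0.57) and endothelial (0.91) markers did not. The lowest median lies within the spread of its members, a limit weighed only after the results were seen. With that limit this source stays open too. A response to interferon in early pregnancy may also account for the change of the interferon list and was not tested apart from the batch.

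The 146 genes lower in uterine Treg than in CD4conv do not, as a set, follow the sequencing batch. If batch set them, pregnant uterine Treg of batch 1 would exceed non-pregnant uterine Treg of batch 2 by about 4.45 on the log2 scale; the median of the 146 genes was 0.33 (quartiles -0.30 and 0.97). For the 10 genes higher in uterine Treg it was 0.033, where batch would need a size of 3.22. Plasmacytoid dendritic cells among the CD4conv, which carry CD4 and which no named gate removes, are a candidate source. Of 13 markers, listed after the genes were seen, 12 are among the 146, 2 are also in the interferon list and 7 exceed 20 CPM in lymph node Treg. For 10 of the 13, each CD4conv library lay above each Treg library, as for Siglech (764 CPM or more against at most 88.1 CPM). Irf7, Tcf4 and Pacsin1 overlapped. The mean of the 13 markers was higher in every CD4conv library than in every Treg library (lowest minus highest 2.85 on the log2 scale). As the markers were picked after the genes were seen, these values are no separate test. Macrophages in some CD4conv libraries stay open as well: the mean of macrophage and dendritic cell markers, a list fixed before, was not higher in every CD4conv library than in every Treg library (lowest minus highest -0.40 on the log2 scale). Such cells would dilute T cell genes, and the T cell identity list was higher in uterine Treg by a median of 0.36 (2 of 13 genes, 4 adjusted over the list alone, adjusted p = 0.545 with an estimated correlation), which leaves this and a true difference between the cell types open.

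Reads in silent receptor genes may come from genomic DNA. Other silent classes were read too: the lowest median rate over libraries, for keratin-associated proteins, was 0.496 of the receptor rate, and that of bitter taste receptors 1.38. In uterine Treg 1 and 2 that of keratin-associated proteins was lower, 0.103 and 0.246. DNA of male embryos is excluded as the source, since single-copy Y-linked genes reached at most 0.00802 of the receptor rate. No biological explanation was tested.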
